A study of Mus musculus with 10 samples.

How the data were processed

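The RNA-seq part measured polyadenylated RNA of mouse embryonic fibroblasts in 8 libraries: mock-transfected at 37 °C, mock-transfected at 32 °C, siRNA against Cirbp at 37 °C and siRNA against Rbm3 at 37 °C, 2 each. The PAR-CLIP part holds 1 library of FLAG-tagged Cirbp and 1 of FLAG-tagged Rbm3, both listed at 37 °C.

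The FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) were used as deposited by the authors, in tables of the kind Cufflinks writes, with 1 value for each of 28702 RefSeq transcripts. Per the labels, reads were aligned to mm9 with TopHat 1.1.2, while the version of Cufflinks and the release of the annotation are not stated. The coverage column, as deposited by the authors, is the mean read depth per base of a transcript, not scaled by library size. Transcript length, per the file headers, is in nt. The score of each PAR-CLIP site, as deposited by the authors, is a whole number from 1 to 1000 whose scale is not stated. Per the file headers the sites are on mm9 and passed a filter whose meaning is not spelled out, and the caller of the sites is not stated.

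The ratio of coverage to FPKM is 1 constant per library and gave the number of mapped fragments. These were 27.8 and 27.0 M fragments for mock 37 °C, 27.7 and 26.2 for mock 32 °C, 26.5 and 27.8 for siCirbp and 26.7 and 24.8 for siRbm3. Reads per gene recovered from it for genes of 1 transcript under 100 reads were whole numbers within 0.05 in 92.6% to 93.2% of cases. How reads with several best positions were counted is not stated.

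FPKM were summed per gene over its listed transcripts, giving 22552 genes. The 10901 with a mean of at least 1 FPKM over the 8 libraries were tested, 159 of which have only transcripts under 200 nt. Limma 3.58.1 in R 4.3.3 was fitted on log2(FPKM + 1) with 4 group means, 4 residual degrees of freedom and empirical Bayes moderation with trend and robust options. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 comparisons were 32 °C, siCirbp and siRbm3 against mock 37 °C, and siCirbp against siRbm3. Error bars are the SD of 2 libraries. Whether the replicate numbers pair libraries is not stated, so no pairing was assumed in the main fit. Correlations of residuals between libraries with the same number ran from -0.15 to 0.09, which cannot exclude pairing. The fit was tested on simulated data of the same spread.

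Gene lists were fixed before the data were examined, as were the comparisons, the tests and all alternatives not named here as later ones. The lists were clock, pre-mRNA 3' end processing, SR proteins and CLK kinases, cytosolic heat shock proteins, ER stress and integrated stress response, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, G1/S and DNA replication, G2/M and mitosis, p53 targets, interferon response, NF-kB inflammatory genes, collagens and extracellular matrix, matrix proteases, SRF and YAP targets, glycolysis and hypoxia, cytosolic ribosomal proteins, nuclear-encoded respiratory chain and replication-dependent histones. Markers of macrophages, epithelium, endothelium, muscle, adipocytes and neural cells had fewer than 5 measured members each and got values only. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over all lists and comparisons, and again with the correlation estimated from the data. The version with an estimated correlation called 0 lists in each comparison. A call lost under it therefore does not by itself show that correlated genes made the signal. Fry of limma tests whether the genes of a list move on balance one way and compares them with no other genes. Members are counted as past limma's adjusted p over all genes and adjusted over the list alone.

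Genes are named by a rule fixed before the data were examined. Cirbp and Rbm3 are always named. Per comparison, the 8 largest rises and 8 largest falls are named among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap of libraries. Up to 4 members of each described list with the smallest adjusted p follow. With fewer than 5 genes past the threshold, the 5 smallest p in each direction are given as values. For PAR-CLIP these are the 5 highest-scoring sites, the 5 genes with most sites and the 5 highest-scoring genes bound by both proteins. Exceptions are stated where they occur.

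Shared mock 37 °C controls were addressed by 100 simulations of unchanged groups with shared controls. The controls were simulated as well, and all libraries were drawn with the same spread per gene. Transcript shares were tested with limma on the log2 ratio of a transcript's FPKM + 1 to that of the rest of its gene, for genes of at least 5 FPKM with at least 2 transcripts of 10% or more. Usage of the most distal 3' end was added after the data were seen, for genes with a distal share of 10% to 90% whose strand follows from transcripts that share a start and differ at the other end.

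PAR-CLIP sites were intersected with bedtools 2.31.1 on the same strand with at least 1 nt shared. A gene holds a site if the site overlaps the locus of any of its transcripts. Site positions are those of the nucleotide marked in the file within the locus of the gene's most expressed transcript, introns included, for sites in exactly 1 gene, with the site's own strand. Shares have exact Clopper-Pearson 95% intervals. Overlaps of genes were compared by Fisher's exact test and by 10000 draws matched on FPKM deciles. Medians of bound genes were compared with 10000 lists matched on 20 FPKM bins. The comparison of 5' ends was added after the data were seen, with intervals from 2000 bootstraps over genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

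Alternatives for expression were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median centring, quantile normalization, moderation without trend and robust options, only the 2 groups of a comparison in the fit, the highest transcript only, values with another status than OK left out, the replicate number as a block, a 2-fold minimum and leaving out each library. For sites they were a shared 50% of each site, a distance of 100 nt, either strand, sites scoring at least the median, at least 2 sites, at least 5 FPKM and windows of 500 and 2000 nt. For transcript shares they were 10 FPKM, a pseudocount of 0.1 and the block. Chosen after the data were seen were genes with a transcript of at least 200 nt, crossed pairing of siCirbp and siRbm3, sites in exactly 1 gene, draws matched on length, a minimum of 100 nt between 3' ends, and removal of the trend of each library on log2 transcript length by loess with a span of 0.4. Sequence motifs at sites were not analysed here, as they need the genome sequence.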

Results

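The series holds 10 samples of mouse embryonic fibroblasts. Polyadenylated RNA was sequenced from 8 libraries in 4 groups of 2. These were mock-transfected cells at 37 °C, mock-transfected cells at 32 °C, and cells at 37 °C after siRNA against Cirbp or Rbm3, a pair of RNA-binding proteins known to be induced by mild cold. The other 2 samples are PAR-CLIP libraries of cells that express FLAG-tagged Cirbp or FLAG-tagged Rbm3, listed at 37 °C. In PAR-CLIP, RNA that holds 4-thiouridine is crosslinked to a protein and the bound sites are read by sequencing. Depth, recovered from the ratio of coverage to FPKM, ran from 24.8 to 27.8 M fragments per RNA-seq library. Of 22552 listed genes, 10901 had a mean FPKM of at least 1 and were tested with limma. The labels do not say whether libraries of a group are separate cultures or whether the numbers of the siRNA libraries mark different siRNAs. The p-values therefore measure only the spread between these libraries. The median absolute log2 difference between the libraries of a group was 0.0879 for mock 37 °C, 0.107 for mock 32 °C, 0.261 for siCirbp and 0.313 for siRbm3. Fold changes against mock 37 °C were lower for longer transcripts. Spearman correlations across genes, which are not independent replicates, were -0.340 for 32 °C, -0.265 for siCirbp and -0.333 for siRbm3. All rest on the same mock 37 °C libraries, so they are not separate findings and may reflect a property of those controls. Removing that trend is an alternative chosen after the data were seen. Gapdh, which has many near-identical copies in the genome, was listed at 0.104 to 0.451 FPKM. Ribosomal protein genes, which have many such copies as well, had a median of 10.1 FPKM in mock 37 °C, and their values may rest on only part of their reads.

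The targeted genes were read first in every library. Cirbp stood at 15.9 and 17.1 FPKM in mock 37 °C, at 34.5 and 37.2 in mock 32 °C, at 10.8 and 6.07 in siCirbp, and at 13.8 and 23.8 in the libraries labelled siRbm3. It rose at 32 °C by a log2 fold change of 1.07 (SE 0.30, n = 2 per group, limma adjusted p = 0.0313). In siCirbp it was lower in both libraries by -0.94 (SE 0.30), which did not pass (limma adjusted p = 0.116). Rbm3 over all its transcripts stood at 1.85 and 2.21 FPKM in mock 37 °C, 3.64 and 3.20 in mock 32 °C, 5.54 and 7.55 in siCirbp, and 3.05 and 1.16 in the libraries labelled siRbm3. Replicate 1 of the siRbm3 label was therefore above both mock 37 °C libraries, against its label. No Rbm3 difference passed limma, with log2 fold changes of 0.55 at 32 °C (adjusted p = 0.191), 1.31 in siCirbp (adjusted p = 0.0588) and -0.03 for the siRbm3 label (adjusted p = 0.971). With the highest transcript only, the direction of Rbm3 at 32 °C turned to lower. The call for Cirbp at 32 °C was lost without any 1 of the 4 mock libraries (adjusted p from 0.117 to 0.168), and without replicate 1 or 2 of the siRbm3 label the Cirbp value in siCirbp passed (limma adjusted p = 0.0481 or 0.0478). Without these libraries Rbm3 passed as well, at 32 °C (limma adjusted p = 0.0417 or 0.0416) and in siCirbp (0.0137 or 0.0136). Between siCirbp and the siRbm3 label Cirbp differed by -1.07 (limma adjusted p = 0.233) and Rbm3 by 1.34 (0.221), and both passed without replicate 1 of the siRbm3 label (0.0207 and 0.00474).

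Rbm3 reads were split over transcripts that share 1 end of the locus on mm9 chromosome X. The 2900 nt transcript, at 7716101 to 7722928, carried 78.3% and 76.3% of Rbm3 FPKM in mock 37 °C, 16.1% and 19.8% in mock 32 °C, 83.6% and 91.0% in siCirbp, and 91.1% and 88.9% in the libraries labelled siRbm3. The shorter transcripts together, at 7719482 to 7722928, stood at 0.401 and 0.522 FPKM in mock 37 °C, 3.06 and 2.57 in mock 32 °C, 0.908 and 0.677 in siCirbp, and 0.272 and 0.128 in the libraries labelled siRbm3. This split was chosen after its values were seen and has no test of its own. The FPKM are low, and the split depends on how reads were assigned between transcripts.

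**Figure D1:**
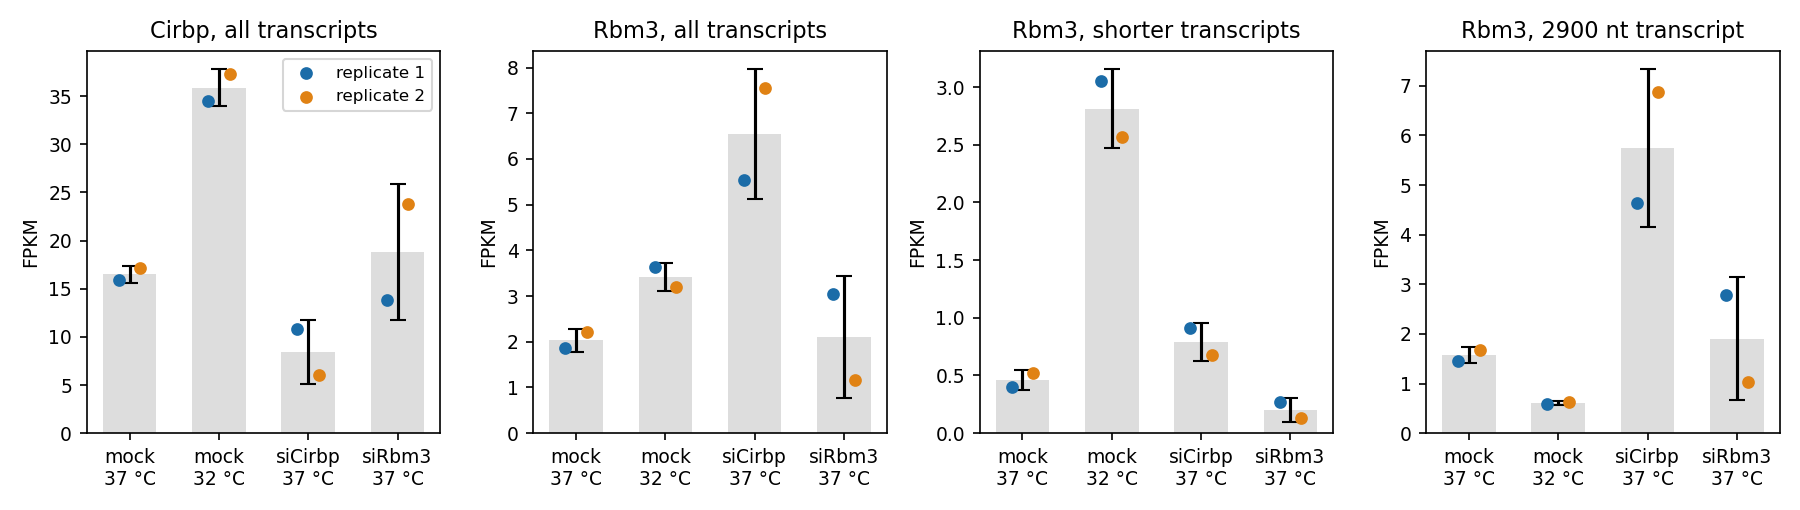
Each panel plots FPKM on the y axis for the 4 RNA-seq groups on the x axis; points are the 2 libraries, bars their mean and error bars the SD. The shorter Rbm3 transcripts stand at 3.06 and 2.57 FPKM at 32 °C and at 0.272 and 0.128 under the siRbm3 label, while the 2900 nt transcript is highest in siCirbp.

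The first comparison asks which mRNAs differ when mock-transfected fibroblasts are kept at 32 °C and not at 37 °C. At 32 °C all 24 measured mitotic genes and 18 of 21 glycolysis and hypoxia genes fell, and 15 of 21 p53 targets rose. The calls of these lists were lost with an estimated correlation (adjusted p = 0.300, 0.669 and 0.300). For p53 targets the estimate was -0.0091, below the preset 0.01, so correlated genes do not account for that loss. The largest rises among called genes were those of Gm11428, from 0.345 to 17.1 FPKM (log2 fold change 3.71), and Eda2r, a TNF receptor family member known as a p53 target, from 3.61 ± 0.36 to 42.7 ± 2.0 FPKM (SD, n = 2 per group; log2 fold change 3.25, SE 0.24). Anxa8 rose by 2.73, Crct1 by 2.69, E230016K23Rik by 2.65 and the collagenase gene Mmp13 by 2.63. The short noncoding RNAs Snord15a (log2 fold change 2.82) and Rprl3 (2.69) rose as well. Gys1, the muscle-type glycogen synthase, fell from 134 ± 2.3 to 13.8 ± 0.063 FPKM (log2 fold change -3.19, SE 0.47), and Pfkl, a phosphofructokinase of glycolysis, fell from 118 ± 13 to 13.5 ± 0.84 (-3.03, SE 0.29). The proliferation marker Mki67 fell by 3.01, the mitotic ubiquitin-conjugating enzyme gene Ube2c by 2.79 and the hypoxia-responsive Ndrg1 by 2.76 on the log2 scale. Mir133a-2, Mir210 and Snora81 were listed at 0 in both 32 °C libraries. They rested on 1 to 3 reads per mock 37 °C library, so no fold is given for them.

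In this comparison limma called 3573 genes, 1420 higher and 2153 lower at 32 °C, of which 320 and 813 changed at least 2-fold. The split by direction depends on the scaling. Median centring, which moved the median log2 fold change by 0.125, gave 2110 higher and 1721 lower, and quantile normalization 1893 and 1994. Removal of the length trend gave 1498 and 1865, with 2666 genes shared with the 3573. Without 1 library at a time the count was 655 or 398 (mock 37 °C replicate 1 or 2 left out) and 826 or 395 (mock 32 °C replicate 1 or 2 left out).

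**Figure D2:**
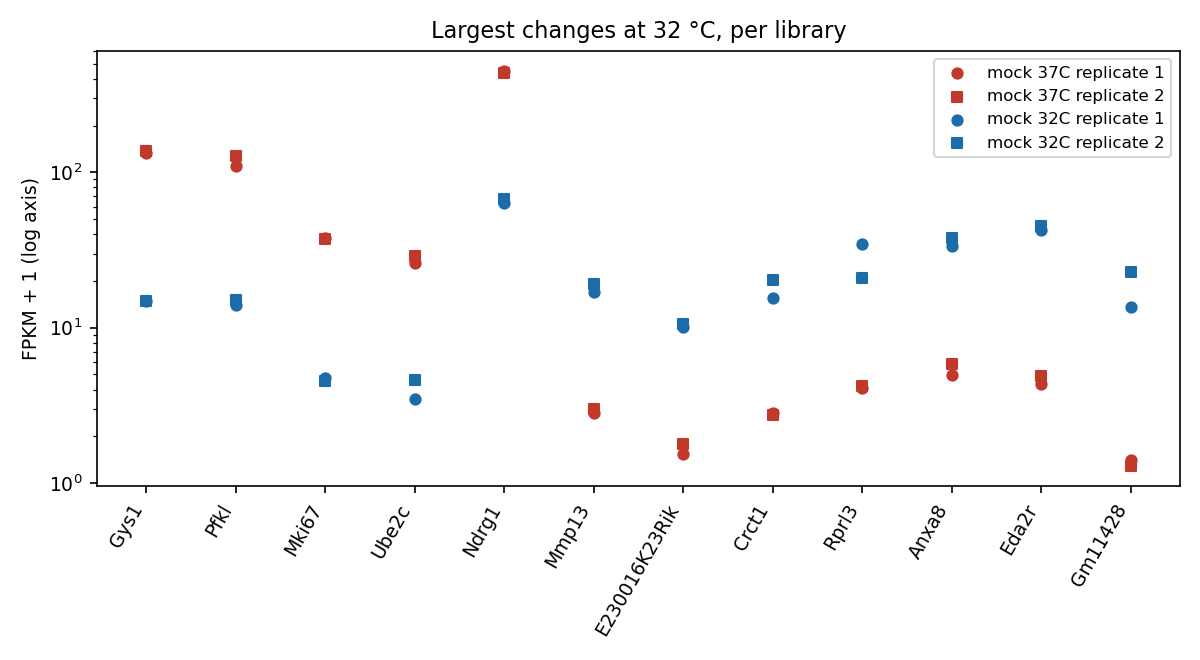
FPKM + 1 on a log y axis in the mock 37 °C and mock 32 °C libraries, 1 point per library, for genes with a transcript of at least 200 nt and the largest falls and rises at 32 °C. Gys1 lies at 134 FPKM on average at 37 °C and 13.8 at 32 °C, and Eda2r at 3.61 and 42.7.

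All 24 measured genes of G2/M and mitosis fell at 32 °C, with a median log2 fold change of -2.09. Cyclin A2 (Ccna2) went from 40.9 ± 1.8 to 6.63 ± 0.78 FPKM, the mitotic kinase genes Aurkb from 14.1 ± 0.24 to 1.84 ± 0.072 and Plk1 from 14.7 ± 0.14 to 1.94 ± 0.45 (SD, n = 2 per group). The camera test of limma called this list (adjusted p = 3.59e-15; adjusted p = 0.300 with an estimated correlation), and 24 genes fell when adjusted over the list alone. Of 24 G1/S and DNA replication genes, 6 fell and none rose (5 fell adjusted over the list alone), among them Mcm5 and Pole. This list was not called (median -0.31, camera adjusted p = 0.111). Among the 21 genes of glycolysis and hypoxia, 18 fell and none rose (19 fell adjusted over the list alone), with a median of -1.41. Camera called this list (adjusted p = 2.39e-07; adjusted p = 0.669 with an estimated correlation). The glucose transporter Slc2a1 went from 204 ± 15 to 41.1 ± 2.3 FPKM, the prolyl hydroxylase P4ha2 from 185 ± 6.6 to 34.0 ± 0.19 and hexokinase Hk2 from 21.2 ± 0.12 to 4.41 ± 0.13.

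Genes of the extracellular matrix went both ways at 32 °C: of 22 collagens and matrix genes 11 fell and 3 rose, with the same counts adjusted over the list alone. Collagen Col1a1 fell from 725 ± 71 to 186 ± 12 FPKM, the crosslinking enzyme Lox from 464 ± 10 to 73.9 ± 1.4 and Col6a2 from 116 ± 9.2 to 32.9 ± 1.0 (SD, n = 2 per group). The 3 that rose, named after their values were seen, were Dcn (log2 fold change 1.02), Postn (0.84) and Timp1 (0.81). The list was called down (median -0.67, camera adjusted p = 0.0189; adjusted p = 0.726 with an estimated correlation). With the length trend removed the median was -0.45 and the list was not called (adjusted p = 0.0881). Of 20 SRF and YAP targets 8 fell and 2 rose (9 and 2 adjusted over the list alone). This list was called down (median -0.59, camera adjusted p = 0.0175; adjusted p = 0.669 with an estimated correlation). The immediate early genes Fos (-2.67), Egr1 (-2.47) and Junb (-2.14) fell, and Ankrd1 rose by 1.83. In fatty acid synthesis and desaturation 9 of 18 genes fell and 1 rose (11 and 2 adjusted over the list alone), with the desaturase Scd2 at -2.07 and Srebf1 at -1.32. The list was called down (median -0.49, camera adjusted p = 0.0468; adjusted p = 0.689 with an estimated correlation). That last call was lost with the length trend removed (median -0.25, adjusted p = 0.176), a replicate block (0.0549), the highest transcript only (0.058), a mean FPKM of at least 5 (0.0746) and a pseudocount of 0.1 (0.0518). It was also lost without mock 37 °C replicate 1 (0.0583) or either library labelled siRbm3 (0.0708 and 0.0591).

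Of 21 p53 targets 15 rose and 1 fell at 32 °C, over all genes and adjusted over the list alone, with a median log2 fold change of 0.87. Besides Eda2r, Ccng1 rose from 31.5 ± 0.41 to 176 ± 18 FPKM, Ei24 from 21.7 ± 0.081 to 53.5 ± 7.8 and Mdm2, the ubiquitin ligase of p53, from 27.2 ± 0.55 to 59.7 ± 1.0 (SD, n = 2 per group). The antiproliferative Btg2, named after its value was seen, was the 1 that fell (-0.74). This list was called up (camera adjusted p = 2.10e-06; adjusted p = 0.300 with an estimated correlation). Of 22 genes of ER stress and the integrated stress response 8 rose and none fell (9 adjusted over the list alone), including the chaperone Hspa5 (1.04), the transcription factor Atf4 (1.18) and asparagine synthetase Asns (2.04). This list was called up (median 0.55, camera adjusted p = 0.00327; adjusted p = 0.669 with an estimated correlation). Among 35 nuclear-encoded respiratory chain genes 8 rose and 1, Uqcrc1, fell (7 and 1 adjusted over the list alone). The list was called up (median 0.45, camera adjusted p = 0.00225; adjusted p = 0.740 with an estimated correlation). The respiratory chain call ended with quantile normalization (adjusted p = 0.106) and with the length trend removed (median 0.052, adjusted p = 0.637).

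The other lists were not called at 32 °C. Of 20 clock genes 2 rose and 6 fell (2 and 7 adjusted over the list alone; median -0.36; camera adjusted p = 0.346). Those with the smallest p, Nfil3 (-1.53), Bhlhe40 (-1.67), Arntl (-0.83) and Per1 (-0.77), fell. Of 22 cholesterol genes 5 rose and 7 fell (7 and 7 adjusted over the list alone), with Srebf2 (-1.30) lower and Ebp (0.80) and Sc4mol (0.85) higher. Their median was -0.03, while camera put the list up (adjusted p = 0.919). Of 14 matrix proteases 4 rose and 4 fell, with the same counts adjusted over the list alone (median 0.45, camera adjusted p = 0.610). Of 18 interferon response genes 4 rose and none fell (3 adjusted over the list alone; median 0.31, camera adjusted p = 0.0724). Medians of the remaining lists were 0.04 for pre-mRNA 3' end processing (mean -0.08), 0.24 for SR proteins and CLK kinases, -0.15 for cytosolic heat shock proteins, -0.32 for NF-kB inflammatory genes, 0.13 for cytosolic ribosomal proteins and -0.61 for replication-dependent histones. Their camera adjusted p ran from 0.269 to 0.935. Markers of other cell types had fewer than 5 measured members per list and got no set test. Of these, Sox2 (31 to 10.7 FPKM), Nes (20.6 to 6.85), Lipe (9.01 to 2.89) and Krt19 (1.52 to 0.0611) fell at 32 °C. The measured markers that did not pass, as mock 37 °C and 32 °C means, were Cd68 (9.98 and 19.2), Cd14 (8.82 and 13.7), Fabp4 (10.1 and 26.7), Flt1 (15.2 and 10.6), Egfl7 (2.62 and 1.31), Eng (1.55 and 1.29), Tnnt2 (49.3 and 37.8), Tnnc1 (2.44 and 2.76) and Des (0.715 and 1.15).

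**Figure D3:**
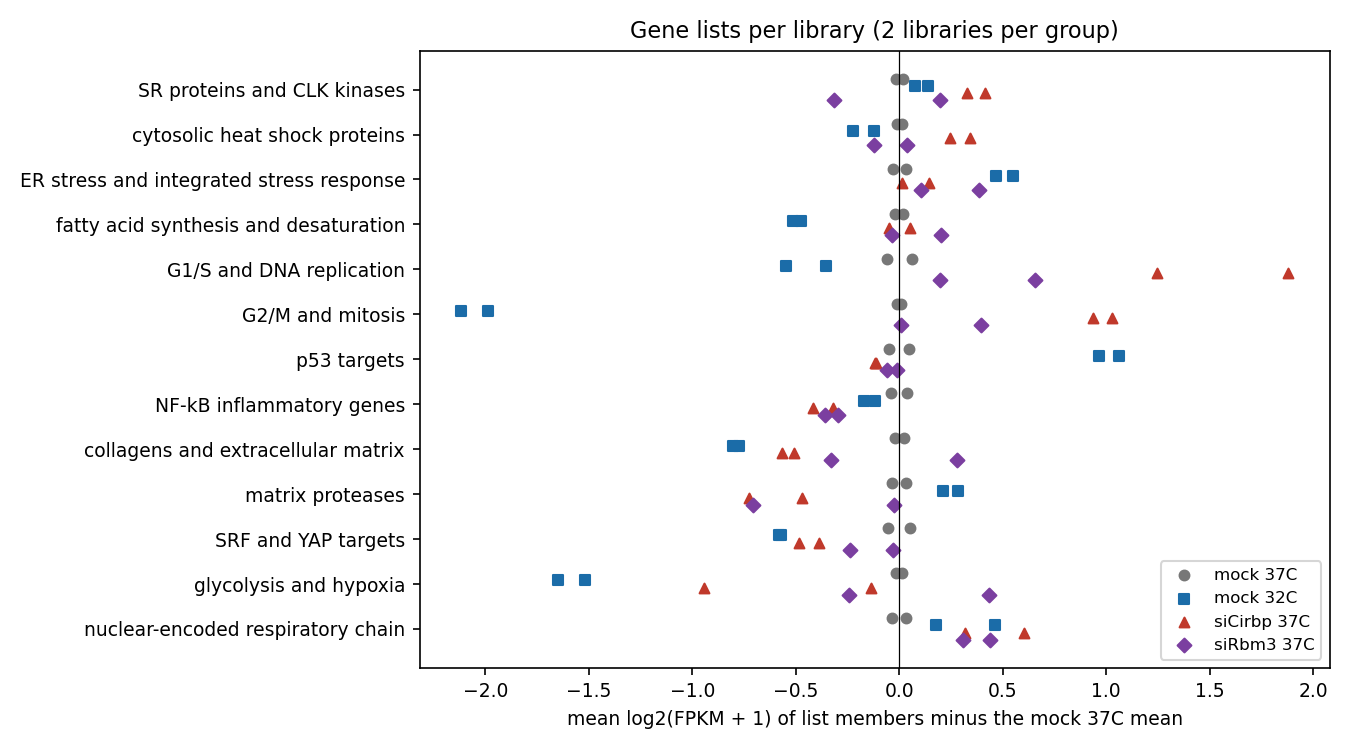
The x axis is the mean log2(FPKM + 1) of a list's members in 1 library minus their mean in mock 37 °C, the y axis names each list called in at least 1 comparison, and symbols mark the 4 groups. G2/M genes lie at -2.12 and -1.99 in the 32 °C libraries and at 0.937 and 1.03 in siCirbp, and the libraries labelled siRbm3 lie on opposite sides of 0 for collagens (-0.332 and 0.280).

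The second comparison asks which mRNAs differ after siRNA against Cirbp at 37 °C. The controls were mock-transfected, and no group with a control siRNA is listed. An effect of the target can therefore not be told apart from a general effect of siRNA. Many genes of DNA replication (19 of 24) and of mitosis (12 of 24) rose. The calls of both as lists were lost with an estimated correlation (adjusted p = 0.589 and 0.300). Mcm5, a subunit of the replicative helicase, rose from 9.62 ± 1.6 to 54.7 ± 17 FPKM (SD, n = 2 per group; log2 fold change 2.36, SE 0.29, limma adjusted p = 0.0211). Mcm3, the ribonucleotide reductase subunit Rrm2, 2810417H13Rik and Mcm10 rose by 2.22, 2.20, 2.13 and 1.87. The galectin gene Lgals3 fell from 84.4 ± 1.4 to 7.80 ± 0.21 FPKM (-3.28, SE 0.59, limma adjusted p = 0.0408). It stood at 17.5 and 80.9 in the libraries labelled siRbm3. Sprr2k fell by 2.51, Ptchd1 by 2.01, the chemokine gene Cxcl1 by 1.98 and the matricellular gene Cyr61, a YAP target, by 1.97 on the log2 scale. Mir29c and Snora5c were listed at 0 in mock 37 °C and Mir133a-2, Mir210 and Snora81 at 0 in siCirbp. Snora5c rested on 1 read per siCirbp library, and no fold is given for these RNAs.

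Limma called 370 genes in siCirbp, 302 higher and 68 lower, of which 154 and 44 changed at least 2-fold. In data simulated for this comparison over 10901 genes, 3.03% of genes with a log2 fold change of 0.5 were recovered, 67.2% of those with 1 and 97.0% of those with 2. The split was 213 and 76 with median centring and 280 and 124 with quantile normalization. With the length trend removed it was 50 and 43, and 82 of these 93 genes were among the 370. The count was 57 without filter, 3 with a replicate block and 13 with only 2 groups in the fit. Leaving out any 1 of the 8 libraries moved the count by more than 1.5 times. It was 13 or 15 without mock 37 °C replicate 1 or 2, and 4 without either mock 32 °C library. It was 677 or 8 without siCirbp replicate 1 or 2, and 1612 or 1608 without replicate 1 or 2 of the siRbm3 label.

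Of 24 G1/S and DNA replication genes 19 rose in siCirbp and none fell, and all 24 rose adjusted over the list alone (median 1.55; camera adjusted p = 6.77e-16; adjusted p = 0.589 with an estimated correlation). Gins2 went from 14 ± 2.2 to 44.0 ± 9.6 FPKM and Rrm1 from 27.6 ± 0.026 to 80.3 ± 15 (SD, n = 2 per group). Among 24 G2/M and mitosis genes 12 rose (20 adjusted over the list alone) and none fell (median 1.03; camera adjusted p = 8.73e-13; adjusted p = 0.300 with an estimated correlation). The apoptosis inhibitor and mitotic gene Birc5 went from 38.2 ± 2.5 to 108 ± 0.74 FPKM and Cdk1 from 23.3 ± 1.6 to 57.7 ± 1.4. Respiratory chain genes were called up as a list (median 0.45, camera adjusted p = 8.75e-06; adjusted p = 0.698 with an estimated correlation). Of the 35 members 0 passed limma over all genes and 8 rose adjusted over the list alone. With the length trend removed the median was 0.23 and the call stayed (adjusted p = 3.11e-04).

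Lists called down in siCirbp were NF-kB inflammatory genes, collagens and matrix genes, matrix proteases, SRF and YAP targets, and glycolysis and hypoxia. Of 19 NF-kB inflammatory genes 3 fell, over all genes and adjusted over the list alone: Cxcl1, the prostaglandin synthase gene Ptgs2 (-1.29) and Cxcl5 (-1.08). The list was called with a median of -0.09 (camera adjusted p = 0.00128; adjusted p = 0.300 with an estimated correlation). Of 22 collagens and matrix genes 1, Dcn (-0.89), fell (7 fell and 1 rose adjusted over the list alone; median -0.55; camera adjusted p = 8.75e-06; adjusted p = 0.589 with an estimated correlation). Dcn rose at 32 °C. Of 14 matrix proteases 1, Mmp13 (-0.91), fell (6 adjusted over the list alone; list median -0.60; camera adjusted p = 1.01e-05; adjusted p = 0.664 with an estimated correlation). Of 20 SRF and YAP targets 4 fell, namely Fos (-1.85), Egr1 (-1.81), Cyr61 and Junb (-1.29), and none rose. Adjusted over the list alone 7 fell and 1 rose (median -0.42; camera adjusted p = 1.38e-04; adjusted p = 0.589 with an estimated correlation). Of 21 glycolysis and hypoxia genes 1, Bnip3 (-1.07), fell, and 3 did adjusted over the list alone (median -0.42; camera adjusted p = 1.82e-04; adjusted p = 0.726 with an estimated correlation). Without siCirbp replicate 2 the median turned to 0.033 and the call ended (adjusted p = 0.264).

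Among lists not called in siCirbp, 1 clock gene, Cry1 (0.90), 1 cholesterol gene, Acat2 (0.75), and the ribosomal protein genes Rpsa (0.81) and Rpl30 (0.89) rose. Of the p53 targets Btg2 (-1.45) and Plk2 (-0.92) fell. These were named after their values were seen, and each of these counts was the same adjusted over the list alone. Medians were -0.06 for clock, 0.21 for pre-mRNA 3' end processing, 0.40 for SR proteins and CLK kinases, 0.38 for cytosolic heat shock proteins and 0.04 for ER stress (4 rose and 1 fell adjusted over the list alone). They were 0.12 for cholesterol, 0.01 for fatty acid genes (put down by camera), -0.07 for p53 targets, -0.14 for interferon response, 0.17 for ribosomal proteins and -0.01 for histones, with camera adjusted p from 0.0883 to 0.852. The 3' end processing list (camera adjusted p = 0.111) was called up with the length trend removed (0.0436) and by fry (0.0283), but not with an estimated correlation (0.589).

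The third comparison asks the same for siRNA against Rbm3, and the lack of a control siRNA limits it in the same way. Since the level of Rbm3 over all its transcripts goes against the label in replicate 1, a direction here belongs to the label. Fos and Ptgs2 had the smallest p, with lower values. Limma called 0 genes, with 1451 at an unadjusted p under 0.05 where chance gives 545, and a smallest adjusted p of 0.0859. Values were lower for Fos (13.8 ± 0.17 to 2.77 ± 0.71 FPKM, SD, n = 2 per group), Ptgs2 (60 ± 1.2 to 20.7 ± 3.3), the immediate early gene Ier2 (123 ± 15 to 39.9 ± 3.8), Ptchd1 (5.70 ± 0.45 to 0.828 ± 0.39) and Phex (4.53 ± 0.32 to 1.11 ± 0.24). Those with higher values were Grb10 (1.71 ± 0.045 to 5.26 ± 0.10), cyclin F (Ccnf, 7.98 ± 0.49 to 14.7 ± 0.82), Tusc1, Letmd1 and Scrn1. Without the library labelled siRbm3 replicate 1 limma called 951 genes, 133 higher and 818 lower, and without replicate 2 it called 22. Without mock 37 °C replicate 1 or 2 it called 8 or 12, and without either siCirbp library 1. Removing the length trend moved the median log2 fold change by -0.10 and gave 1 call.

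As lists, G1/S (median 0.49, camera adjusted p = 0.00158; adjusted p = 0.729 with an estimated correlation), G2/M (0.48, camera adjusted p = 0.00457; adjusted p = 0.669 with an estimated correlation) and respiratory chain genes (0.40, camera adjusted p = 4.28e-06; adjusted p = 0.689 with an estimated correlation) were called up under the siRbm3 label. NF-kB inflammatory genes (-0.18, camera adjusted p = 7.74e-04; adjusted p = 0.300 with an estimated correlation) and matrix proteases (-0.21, camera adjusted p = 0.00158; adjusted p = 0.689 with an estimated correlation) were called down. No member of these 5 lists passed limma over all genes. Adjusted over the list alone, 13 G2/M genes rose and 2 fell, 3 NF-kB genes and 4 proteases fell, and 0 members of G1/S and of the respiratory chain passed. The respiratory chain median was 0.14 with the length trend removed, and the call stayed (adjusted p = 3.37e-04). Without replicate 1 of the siRbm3 label the calls of G1/S (adjusted p = 0.686), G2/M (0.917) and proteases (0.641, median turned to 0.15) were lost. The protease call also ended at a mean FPKM of at least 5 (adjusted p = 0.0655, median -0.089). The number of called lists was 3 without replicate 1 and 8 without replicate 2. The 14 lists not called had camera adjusted p from 0.0951 to 0.981. Camera compares a list with the other genes, whose median was 0.12 here. It put the clock (median 0.19), heat shock (0.03), p53 (0.11), collagen (0.05), SRF and YAP (0.03) and ribosomal (0.14) lists down while their medians were above 0. Removal of the length trend turned the ribosomal median to -0.10, and the list was called down (adjusted p = 0.0368). Medians of the other lists were 0.16 for pre-mRNA 3' end processing, -0.04 for SR proteins and CLK kinases, 0.30 for ER stress, 0.20 for cholesterol, 0.19 for fatty acid genes, -0.05 for interferon response, 0.18 for glycolysis and hypoxia and -0.02 for histones. Adjusted over the list alone, 2 SRF and YAP targets rose and 4 fell, 1 fatty acid gene rose and 1 fell, and 1 p53 target fell, with none in the other lists not called.

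The direct comparison sets siCirbp against the libraries labelled siRbm3. By camera, the replication and mitosis lists were higher in siCirbp and the collagen and matrix list lower. No member of these lists passed over all genes, and the calls were lost with an estimated correlation (adjusted p = 0.589, 0.300 and 0.589). The 4 genes called were all short RNAs, named after their values were seen. Snora5c and Mir29c were listed at 0 under the siRbm3 label, and Mir210 and Mir133a-2 at 0 in siCirbp. Among genes with a transcript of at least 200 nt, an alternative chosen after the data were seen, limma called 0 genes. Over all genes 1654 had an unadjusted p under 0.05 where chance gives 545. Limma called 7 genes with the replicate number as a block in these groups alone, and 4 with the numbers crossed, a pairing tried after the data were seen. Data simulated with known changes in siCirbp alone gave 9 false calls in this comparison, with 10901 genes tested. The known changes enter this comparison too, and the adjustment allows more false calls where more true ones are made. The 9 therefore set no chance level for the 4 genes called. Of the remaining genes with the smallest p, values were higher in siCirbp for 2610039C10Rik, Birc5 (108 ± 0.74 against 57.9 ± 2.2 FPKM, SD, n = 2 per group) and the DNA polymerase subunit gene Pole2 (6.97 ± 0.83 against 2.64 ± 0.17). They were lower for Psca (1.80 ± 0.22 against 5.83 ± 0.18), mesothelin Msln (12.1 ± 2.5 against 37.6 ± 5.5) and the collagen Col12a1 (27.6 ± 0.81 against 79.0 ± 21). G1/S genes were called higher in siCirbp (median 1.08, camera adjusted p = 3.47e-17; adjusted p = 0.589 with an estimated correlation). So were G2/M genes (0.64, camera adjusted p = 2.19e-13; adjusted p = 0.300 with an estimated correlation) and SR proteins and CLK kinases (0.48, camera adjusted p = 0.00101; adjusted p = 0.664 with an estimated correlation). Cytosolic heat shock proteins were called higher as well (0.25, camera adjusted p = 0.00266; adjusted p = 0.514 with an estimated correlation).

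Lists called lower in siCirbp than under the siRbm3 label were collagens (median -0.60, camera adjusted p = 1.19e-05; adjusted p = 0.589 with an estimated correlation), SRF and YAP targets (-0.40, camera adjusted p = 8.39e-04; adjusted p = 0.589 with an estimated correlation) and glycolysis and hypoxia (-0.63, camera adjusted p = 8.73e-06; adjusted p = 0.689 with an estimated correlation). No member of the 7 lists passed over all genes. Adjusted over the list alone, 23 G1/S and 17 G2/M genes were higher, 7 collagens and matrix genes lower and 1 higher, and 1 glycolysis gene lower. None passed in the SR protein, heat shock and SRF lists. The glycolysis call was lost without siCirbp replicate 2 (adjusted p = 0.121). The libraries labelled siRbm3 stood on opposite sides of mock 37 °C, as list means in replicates 1 and 2, for SR proteins (0.196 and -0.316), collagens (-0.332 and 0.280), glycolysis (-0.242 and 0.432) and heat shock proteins (0.0375 and -0.119). Without replicate 2 of the siRbm3 label the medians were 0.19, -0.28, -0.33 and 0.30, and without replicate 1 they were 0.82, -0.89, -0.82 and 0.15, in the same order, with all these calls kept. The count of changed genes was 2132 without the library labelled siRbm3 replicate 1, 9 without replicate 2 and 10 without siCirbp replicate 2. The 12 lists not called had camera adjusted p from 0.056 to 0.799. Adjusted over the list alone, 1 fatty acid gene was higher and 1 protease lower in these. The interferon list had a median of -0.07 and a mean of 0.034.

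The 3 comparisons share the mock 37 °C libraries, which alone correlates their fold changes. Across 10901 genes, which are not independent replicates, Pearson's r between 32 °C and siCirbp was 0.285 and Spearman's rho 0.284. Simulated unchanged groups that shared simulated controls gave 0.503 and 0.472 on average over 100 simulations. The covariance was 0.125 against 0.0894. For 32 °C and the siRbm3 label r was 0.118 and rho 0.0144 (0.498 and 0.471 simulated; covariance 0.0427 against 0.0881). It turned to -0.014 among genes with a transcript of at least 200 nt. For siCirbp and the siRbm3 label r was 0.533 and rho 0.533 (0.494 and 0.470 simulated; covariance 0.148 against 0.0877). Of the called genes, 65 were higher at 32 °C and in siCirbp (39.3 if the lists were independent) and 32 lower in both (13.4). A further 104 were lower at 32 °C and higher in siCirbp (59.6 if independent), and 10 higher at 32 °C and lower in siCirbp (8.86). Simulated unchanged groups shared 0.02 higher and 0.03 lower calls on average. Hardly any gene can be called in unchanged groups, so these values give no expected overlap for groups with changed genes. Dividing the 2 control libraries would leave 1 for each comparison and was not done, so part of any excess may come from them. All simulated libraries had the same spread per gene. The median absolute log2 difference was 0.0879 between the mock 37 °C libraries, 0.261 for siCirbp and 0.313 for siRbm3. The simulated correlations and covariances may therefore be too high, and no conclusion is drawn from values near or below them. A general effect of siRNA would also be shared by siCirbp and the siRbm3 label.

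Transcript shares address which isoforms differ, as the series concerns alternative polyadenylation. Isoforms may differ at the start or inside the locus as well as at the 3' end. Among 2936 transcripts of 1333 genes, limma called 7 transcripts of 5 genes at 32 °C and 0 in each other comparison. There 334 (siCirbp), 134 (siRbm3 label) and 294 (siCirbp against siRbm3 label) had an unadjusted p under 0.05, where chance gives 147. In Fam120b the transcript at mm9 chromosome 17, 15533210 to 15570545, made up 52.7% ± 4.0 of the gene's FPKM at 37 °C and 0.00035% ± 0.00045 at 32 °C (SD, n = 2 per group). In Pcx, pyruvate carboxylase, the transcript from the start site at chromosome 19, 4510472 to 4621752, made up 99.3% ± 0.95 at 37 °C and 0.0029% ± 0.00012 at 32 °C. In the p53 target gene Cdkn1a the transcript at chromosome 17, 29230717 to 29237667, went from 99.4% ± 0.90 to 61.6% ± 4.2. In each of these genes the other transcript shares the higher coordinate of the locus. Its lower coordinate is 15533166 in Fam120b, 4594319 in Pcx and 29227931 in Cdkn1a. These calls therefore do not by themselves show a change of polyadenylation. Shares also depend on how reads were assigned between overlapping transcripts, and the trend of fold changes on transcript length was not removed from them. The other genes were Ctage5 and Mtm1, and all 5 were named after their values were seen. The count at 32 °C was 0 without mock 32 °C replicate 1, 2 without mock 32 °C replicate 2 or without either siCirbp library, and 4 transcripts with the replicate number as a block. In siCirbp it was 7 or 2 without mock 37 °C replicate 1 or 2. It was 2 for the siRbm3 label without mock 37 °C replicate 2 or either mock 32 °C library, and 2 between siCirbp and the siRbm3 label without either mock 32 °C library.

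Usage of the most distal 3' end, a test chosen after the data were seen, could be computed for 202 genes whose strand follows from transcripts with a common start. At 32 °C limma called 19, with the share of the distal end higher in 6 and lower in 13. Fold changes at 32 °C were lower for longer transcripts (Spearman -0.340), and that trend was not removed here. Where the transcript with the distal end is the longer one, the trend alone would lower its share. The split by direction can therefore not be told apart from it. In siCirbp it called 8, higher in 6 and lower in 2, and under the siRbm3 label 5, higher in 3 and lower in 2. Between siCirbp and the siRbm3 label limma called 0, with 33 at an unadjusted p under 0.05 where chance gives 10.1. With the replicate number as a block, limma called 2 in siCirbp and 0 under the siRbm3 label. The protocadherin gene Pcdh7 had 52.8% ± 3.5 of its FPKM at the distal end at 37 °C, 24.8% ± 1.9 at 32 °C, 23.6% ± 3.8 in siCirbp and 29.3% ± 5.6 under the siRbm3 label (SD, n = 2 per group), each called. All these Pcdh7 calls rest on the same mock 37 °C libraries. Its ends lie 402775 nt apart, in transcripts of very different extent. Arrdc4 went from 42.9% ± 1.1 to 18.7% ± 1.3 at 32 °C. In siCirbp, Caprin1 went from 50.1% ± 0.39 to 66.2% ± 1.1 and Fnbp1 from 67.8% ± 0.99 to 91.5% ± 3.1. A version with ends at least 100 nt apart, tried after these calls were seen, gave 23, 10, 4 and 4 of 193 genes. Without 1 library at a time the 32 °C count was 1 or 5 (mock 37 °C replicate 1 or 2), 10 or 2 (mock 32 °C replicate 1 or 2) and 42 or 41 (replicate 1 or 2 of the siRbm3 label). The siCirbp count was 0 without mock 37 °C replicate 1 or siCirbp replicate 1, 2 without mock 37 °C replicate 2 or either mock 32 °C library, and 22 without either library labelled siRbm3. The count for the siRbm3 label was 0 without any 1 of the mock and siCirbp libraries and 11 without its replicate 1. Between siCirbp and the siRbm3 label it was 1 without siCirbp replicate 2, and 29 or 2 without replicate 1 or 2 of the siRbm3 label.

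PAR-CLIP asks where each protein binds. Many sites and genes were shared between the proteins, and Rbm3 sites were found near the 5' ends of genes more often. There were 1941 sites for Cirbp and 2118 for Rbm3, from 1 library each with no replicate and no control library. Their depth is unknown, and intervals cover counting error only. On the same strand, 366 Cirbp sites, 18.9% (95% Clopper-Pearson interval 17.1 to 20.7), overlapped an Rbm3 site. The same number of Rbm3 sites, 17.3% (15.7 to 19.0), overlapped a Cirbp site, and 107 marked nucleotides were identical. Sites with a score of 1000, the highest listed, lay on mm9 chromosome 9 at 89697099 to 89697122 in Mir184 for Cirbp, and in the G protein subunit gene Gna13 (chromosome 11, 109257574 to 109257603) and the transcription factor gene Yy1 (chromosome 12, 110054100 to 110054169) for Rbm3. Rbm3 sites with that score lay also in Ythdf2, Fem1b, Nkrf and the overlapping Cpne1 and Rbm12, and further ones outside every listed gene. The other Cirbp sites with that score, on chromosome 11 at 108873186 to 108873363 and chromosome 13 at 54285521 to 54285553, lay outside every listed gene and overlapped an Rbm3 site. So did the next Cirbp sites, on chromosome 17 at 39983818 to 39983863 (score 990) and 39984616 to 39984905 (score 989). Most of the highest-scoring Cirbp sites were of this kind. Without a control library, background cannot be told apart from binding there. Genes with most Cirbp sites were the splicing factor gene Srsf1 (14 sites), the cohesin gene Stag2 (12), Syncrip and Son (11 each) and Matr3, Ddx3x, Eif4g2, Nufip2 and Zc3h7b (10 each). For Rbm3 they were Son (20), the m6A reader gene Ythdf2 (12), Klhl15 and Arid1a (11 each) and Nufip2 and Zbtb10 (9 each). The mRNAs of Cirbp and Rbm3 themselves held 0 sites of either protein.

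Among the 10901 tested genes 907 held a Cirbp site and 958 an Rbm3 site, and 358 held both, where independence gives 79.7 (Fisher's exact test, one-sided, odds ratio 10.2, p = 2.49e-161). In 10000 draws matched on mean FPKM the overlap averaged 91.6 and reached at most 122. Matched also on locus length, an alternative chosen after the data were seen, it averaged 100 and reached 136. Genes with high scores for both included Serbp1, Srsf1, the phosphatase gene Ppp2ca and Ythdf2. Genes with sites were more highly expressed, with a median of 23.7 FPKM with and 12.8 without a Cirbp site, and 18.3 with and 13 without an Rbm3 site.

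Within gene loci, Cirbp sites lay toward the 3' end and Rbm3 sites toward both ends. Of 1527 Cirbp sites placed in 1 gene, 21.3% (95% Clopper-Pearson interval 19.3 to 23.5) lay within 1000 nt of the 3' end, where an even spread over the locus gives 5.59%. Of 1642 Rbm3 sites, 14.5% (12.8 to 16.3) did, where an even spread gives 9.29%. The windows at the 5' end held 3.8% of Cirbp sites and 16.4% of Rbm3 sites, a difference of 12.6 points (95% bootstrap interval over genes 10.4 to 14.8), a comparison added after the data were seen. Where a gene's strand could be read from its transcripts, all 95 Cirbp and 103 Rbm3 sites were on it.

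**Figure D4:**
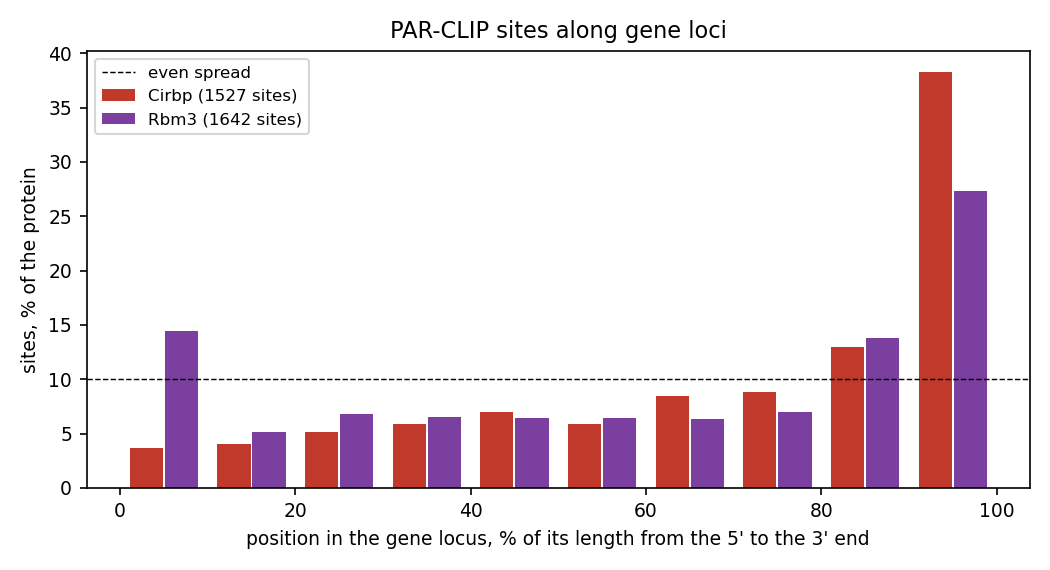
The x axis is the position of a site in its gene locus in percent of the locus length from the 5' to the 3' end, the y axis the percent of a protein's sites in each bin of 10%, and the dashed line an even spread. The bin at the 3' end holds 38.3% of Cirbp and 27.3% of Rbm3 sites, and the bin at the 5' end 3.67% and 14.4%.

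Genes bound by each protein were then set against the expression changes. At 32 °C the 958 genes with an Rbm3 site had a median log2 fold change of -0.22 and the others 0.0018. Of them 266 fell and 71 rose (camera adjusted p = 0.00435; adjusted p = 0.783 with an estimated correlation). No list of 10000 matched on mean FPKM was as low (lowest -0.098). The call ended with the length trend removed (adjusted p = 0.197), and lists matched also on locus and transcript length averaged -0.15, with the median of the bound genes at percentile 0.24. Genes with a Cirbp site had a median of 0.015 at 32 °C (camera adjusted p = 0.855) and those with sites of both -0.09 (0.347). Lists matched on FPKM and both lengths averaged -0.14 and -0.19, with these medians at percentiles 100 and 99.1. In siCirbp, genes with Cirbp sites had a median of 0.095 and the others 0.078 (camera adjusted p = 0.845), genes with Rbm3 sites 0.084 (0.955) and genes with sites of both 0.10 (0.855), so camera detected no difference. Among lists matched on mean FPKM these medians lay at percentiles 39.0, 26.7 and 52.8. Lists matched on FPKM, locus and transcript length, chosen after the data were seen, had lower medians. They averaged 0.027 for Cirbp sites, 0.036 for Rbm3 sites and 0.012 for both, and each bound set lay at percentile 100 of 10000 lists matched in this way. With the length trend removed, genes with Cirbp sites were called up at 32 °C and in siCirbp, and genes with sites of both in siCirbp (adjusted p = 0.0448 each).

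Under the siRbm3 label genes with an Rbm3 site had a median of 0.060 and were not called (camera adjusted p = 0.145). That median lay below every list matched on FPKM (lowest 0.098) and at percentile 0.01 of lists matched also on length. Genes with Cirbp sites (median -0.026, adjusted p = 2.72e-04) and with sites of both proteins (-0.049, adjusted p = 2.72e-04) were called lower by camera (adjusted p = 0.783 with an estimated correlation for each), while the remaining genes had medians of 0.13 and 0.12. Both were higher in siCirbp than under the siRbm3 label (medians 0.15 and 0.15, camera adjusted p = 2.72e-04 and 4.25e-04; adjusted p = 0.783 with an estimated correlation for each). Without the library labelled siRbm3 replicate 2 the medians against mock 37 °C turned to 0.078 and 0.087 and all 4 calls were lost (adjusted p = 0.937). Without siCirbp replicate 2 the pair in the direct comparison was lost (adjusted p = 0.195 and 0.257). With the length trend removed the call of sites of both under the siRbm3 label was lost (adjusted p = 0.0772), that of Cirbp sites stayed (0.0448), and both stayed in the direct comparison (3.61e-05 for Cirbp sites and 1.08e-04 for both). Genes with Rbm3 sites were not called in the direct comparison (median 0.041, camera adjusted p = 0.234). Yet that median lay at percentile 100 of lists matched on FPKM and of lists matched also on length.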

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

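Of the tests here, the swap of libraries, mock cells under the siRbm3 label, the long Rbm3 transcript and the score of Rbm3 sites were chosen only after the result was seen.

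The level of Rbm3 in the library labelled siRbm3 replicate 1, 3.05 FPKM, lies above both mock 37 °C libraries. A swap with a siCirbp library is argued against: Cirbp was at most 10.8 FPKM in the siCirbp libraries, below the 15.9 of the lowest mock 37 °C library, so no partner is out of place by this measure. Cirbp in the library in question also lay below 15.9, which limits this cutoff. Mock cells under this label cannot be told apart from a weak knockdown: the median absolute log2 difference from the nearer mock 37 °C library was 0.191, more than the 0.0879 between the mock libraries and less than the 0.212 and 0.221 from the siCirbp libraries. From the other library labelled siRbm3 it was 0.313, the largest of these, so the library lay closer to siCirbp than to its own replicate. Over 245 genes at least 2-fold apart between siCirbp and mock replicate 1, the library had a median shift of 0.82 toward siCirbp. The shift was 0.435 for siRbm3 replicate 2 and 0.084 for mock replicate 2. Whether the mock libraries are separate cultures is not stated, so the spread between mock cultures is unknown. The shorter Rbm3 transcripts stood at 0.272 FPKM, below both mock 37 °C libraries, so the value over all transcripts may come from the 2900 nt transcript, and whether an siRNA reaches it was not tested. These FPKM are low and depend on how reads were assigned between transcripts, so the difference from mock may be counting error.

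Rbm3 sites lie within 1000 nt of the 5' end of a locus more often than Cirbp sites. Shorter loci as the whole cause are argued against: within genes that hold sites of both proteins the difference was 8.14 points (bootstrap interval 5.55 to 10.9). Low-scoring sites as the whole cause are argued against as well, with 9.45 points (7.05 to 12) among sites that score at least the median of their list. A difference in binding between the proteins may therefore be a candidate explanation, as a hypothesis found on the same data, while the depth and the background of either library, each without replicate, stay open.

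Genes with Rbm3 sites, mapped in cells listed at 37 °C, were lower at 32 °C. Membership in the fixed lists as the cause is argued against by the number of members alone: of 958 bound genes 914 lay outside the lists. Those 914 had a median log2 fold change of -0.23, below the lowest of 10000 lists matched on FPKM but not on length. With so few genes left out the median could hardly have moved, so this value adds no further support. Expression level together with length cannot be told apart from an effect of binding: the median of -0.22 lay at percentile 0.24 of lists matched on FPKM, locus and transcript length, yet above the lowest of these (-0.25), and removing the length trend ended the call (adjusted p = 0.00435 before and 0.197 after). No test here separates lower transcript levels from a bias of long transcripts that differs between the 32 °C and 37 °C libraries.

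Differences between siCirbp and the siRbm3 label were tested directly and brought up 7 lists, with median log2 differences of 0.48 for SR proteins and CLK kinases, 0.25 for cytosolic heat shock proteins, 1.08 for G1/S, 0.64 for G2/M, -0.60 for collagens and extracellular matrix, -0.40 for SRF and YAP targets and -0.63 for glycolysis and hypoxia. The same comparison brought up 4 genes, all short RNAs, and the genes with Cirbp sites (median 0.15) and with sites of both proteins (0.15). With an estimated correlation none of these lists or bound sets was called (adjusted p from 0.300 to 0.689 and 0.783), and the libraries labelled siRbm3 stood on opposite sides of mock 37 °C for SR proteins (0.196 and -0.316), collagens (-0.332 and 0.280), glycolysis (-0.242 and 0.432) and heat shock proteins (0.0375 and -0.119). These results rest on labels of which siRbm3 replicate 1 goes against its own target over all Rbm3 transcripts. Over the shorter transcripts it did not, but their FPKM are low and that split has no test. No explanation of these results was tested.

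In data outside the comparisons, 369 Cirbp and 412 Rbm3 sites lay outside every listed gene locus, and 9 Cirbp and 4 Rbm3 sites lay on mitochondrial DNA. Without a control library no background level can be given for these sites.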

How the results depend on the processing

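Of the alternatives, the tests chosen only after the data were seen are those on genes of at least 200 nt, those with the length trend removed, the crossed pairing of siRNA libraries, sites in exactly 1 gene, draws matched on length, and all on 3' end usage. The cause was not tested for any change given here, apart from fewer samples or genes by construction. With all libraries in, the count of 3573 genes at 32 °C stayed within 1.5 times except with only 2 groups in the fit (7557) and a 2-fold minimum (1133). The siCirbp count of 370 went to 57 without filter, 3 with a replicate block, 13 with only 2 groups in the fit, 217 with the highest transcript only, 198 with a 2-fold minimum and 93 with the length trend removed. The count of 0 for the siRbm3 label in limma, with 1451 genes at an unadjusted p under 0.05, went to 1 with a pseudocount of 5, 5 with only 2 groups in the fit, 2 with the highest transcript only and 1 with the length trend removed. Between siCirbp and siRbm3 label the count of 4 went to 7 without filter, 7 with only 2 groups in the fit and 0 with genes of at least 200 nt. Cirbp at 32 °C kept its log2 fold change of 1.07 but not its call without filter (adjusted p = 0.0637) and with a block (0.0555). Rbm3 at 32 °C passed with only 2 groups in the fit (0.55, adjusted p = 0.0013) and was -0.67 with the highest transcript only, and in siCirbp it passed with a pseudocount of 5 (0.71). Under the siRbm3 label Rbm3 changed sign with a pseudocount of 5 (0.0032), quantile normalization (0.026) and the highest transcript only (0.11), and Cirbp with the length trend removed (-0.092). With an estimated correlation 0 lists were called in each comparison, and 4, 4, 1 and 1 with fry, in the order 32 °C, siCirbp, siRbm3 label and siCirbp against siRbm3 label. With the length trend removed 5 lists were called at 32 °C. Of bound gene sets, 0 were called with an estimated correlation and 0 with fry at 32 °C, under the siRbm3 label and between siCirbp and siRbm3 label, and with the length trend removed 2 in siCirbp and 1 under the siRbm3 label. The correlation of 32 °C with the siRbm3 label changed to -0.014 in genes of at least 200 nt. Isoform calls at 32 °C went to 4 with a block. Calls on 3' ends went to 2 in siCirbp and 0 under the siRbm3 label with a block, and to 4 between siCirbp and siRbm3 label with ends at least 100 nt apart. With 50% of each site shared, 16.4% of Cirbp and 15.1% of Rbm3 sites overlapped, within 100 nt 22.8% and 21.4%, and among sites scoring at least the median 16.7% of Cirbp sites. Genes with sites of both were 103 with at least 2 sites and 193 with sites scoring at least the median. Within 500 nt of the 3' end lay 12.3% of Cirbp and 6.46% of Rbm3 sites, within 2000 nt 33.3% and 29.5%, and 24.1% of Cirbp sites scoring at least the median within 1000 nt. Leaving out a library leaves its group with 1 sample, assumed to vary like the other groups. Gene counts then ran from 395 to 5071 at 32 °C, 4 to 1612 in siCirbp, 0 to 951 under the siRbm3 label and 4 to 2132 between the siRNAs. Cirbp ran from 1.02 to 1.13, -1.31 to -0.57, -0.24 to 0.50 and -1.44 to -0.70 in the same order, and Rbm3 from 0.46 to 0.63, 1.11 to 1.5, -0.48 to 0.42 and 0.88 to 1.79. Called lists ran from 3 to 8 under the siRbm3 label and called bound sets from 0 to 3 there and 0 to 3 between the siRNAs, with medians from -0.10 to 0.078 for Cirbp sites and -0.14 to 0.087 for sites of both under the siRbm3 label. Isoform calls ran from 0 to 7 at 32 °C, 0 to 7 in siCirbp, 0 to 2 and 0 to 2, and 3' end calls from 1 to 42, 0 to 22, 0 to 11 and 0 to 29. Of 155 results of named genes, 127 kept direction and side of the threshold with a block, 127 with only 2 groups in the fit, 135 without filter, 147 with the length trend removed, and 96 to 147 without 1 library.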

Other observations

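The genes below were taken from the fixed lists or, for Trp53 and cyclin D1, chosen after their values were seen. At 32 °C the mRNA of p53 itself (Trp53) was lower, at 23.1 and 27.9 FPKM in the mock 37 °C and 16.7 and 16.8 in the mock 32 °C libraries (log2 fold change -0.57, SE 0.18, n = 2 per group, limma adjusted p = 0.0491), while most listed p53 targets rose. Among the targets the cell cycle inhibitor Cdkn1a rose by 1.60 on the log2 scale, and cyclin D1 (Ccnd1), a G1 cyclin, rose by 0.84 (limma adjusted p = 0.011), while the mitotic cyclin Ccna2 fell. Of the NF-kB list Il1rl1 rose (1.61) and Nfkb1 (-1.15), Nfkb2 (-1.37), Nfkbia (-0.67) and Tnfaip3 (-0.58) fell, with the same counts adjusted over the list alone.

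Among cytosolic heat shock proteins the co-chaperone Bag3 (-1.57), Hsp90ab1 (-1.17), Hspa4l (-0.79), Hsph1 (-0.97) and Stip1 (-0.46) fell at 32 °C (3 rose and 8 fell adjusted over the list alone). Of the 3' end processing list the scaffold Sympk (-1.51), the poly(A)-binding protein Pabpc1 (-1.26), Cpsf1 (-0.82) and Cpsf7 (-0.45) fell and none rose (3 fell adjusted over the list alone). Of the SR proteins Srsf5 rose (0.68) and Srsf4 (-0.92) and Srsf9 (-0.87) fell (0 rose and 2 fell adjusted over the list alone). The clock genes Per2 (0.76) and Nr1d2 (0.91) rose, and among interferon response genes Isg15 (1.16), Ifi44 (1.49), Ifi35 (0.87) and Ifit3 (0.80) rose. Of the ribosomal proteins Rps16 and Rpl5 rose and Rpl7 fell (1 rose adjusted over the list alone), and no histone passed.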
